A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

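RNA was taken from pelleted cells of 2 yeast strains, S. boulardii Biocodex and S. cerevisiae BY4741, with 3 libraries each. Per the labels' protocols, RNA was isolated with the RiboPure-Yeast kit and libraries were made with the NuGEN Universal Plus mRNA-Seq kit, and the series' design text names an Illumina NextSeq. Groups and replicate numbers came from the sample titles. The labels do not say whether the libraries of a strain came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

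The authors deposited 1 table of raw read counts per feature for each library, with whole numbers and no normalization. Per the submitters' processing notes, FastQC, TopHat, HTSeq and DESeq2 were used, and versions, settings, genome build, annotation and strand setting are not given in the sources used here. Whether reads of a gene and of an antisense or overlapping neighbour were told apart is therefore unknown. The tables hold no rows for unassigned reads, so library totals are sums over listed features. The deposited gene model file, whose start and end columns are in bp, describes 5614 models on 27 sequences, 389 of them with more than 1 coding part. Its models name neither the genes nor the identifiers of the Biocodex count tables, and number 132 more than the features counted there.

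The plan, fixed before the data were examined, was an edgeR quasi-likelihood test of each gene between strains, a camera test of 36 gene lists, and a count of genes without reads in one strain. It needed features matched by name. The 5482 Biocodex identifiers and the 6572 BY4741 identifiers share 0 names, 0 Biocodex identifiers occur in the reference gene table, and pairing by order was ruled out, so these tests were not run. The comparisons reported instead were chosen after the count tables had been seen, while the samples, the gene lists and the genes of the genotype check were fixed before. The rule for named genes also lost its parts on fold changes. In their place the most abundant BY4741 genes, members with 0 reads and, for some lists, the highest or lowest members were named. For other lists these were left out, and the choice followed no fixed rule and was made after the values were seen. The value of 1 list member is not reported here. The 23 gene pairs were chosen after the most abundant genes had been seen and before their ratios were computed, and SAG1 and the named genes outside the genotype check and these pairs were chosen after their values were seen.

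BY4741 identifiers are systematic names. Of them, 5898 matched the gene table of the S288C assembly R64, which was used for symbols, for coding lengths and for shared 50-mers, and 674 did not. The authors' build is not given, so no coordinates are reported. A gene that shares over 50% of its 50-mers with other genes (169 of the matched genes) is treated as near-identical, and its count as uncertain, because the authors' counting could split or share such reads. Among genes with identical coding copies, the counts of the copies were sometimes close and sometimes far apart.

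Counts were divided by library totals and scaled to CPM, with means and SDs over 3 libraries. Shares of reads in the most abundant features, detected features (at least 10 reads) and totals were compared between strains by exact two-sided permutation tests of 3 against 3, with Benjamini-Hochberg adjustment over 10 measures. Pearson correlations across features used log2 of CPM plus 1. The BCV was the square root of edgeR's common dispersion per strain, with TMM factors and filterByExpr. Medians of gene lists in BY4741 were placed among 10000 random lists of the same size, per library, for lists with at least 4 measured genes. Ratios of gene pairs were taken within each library. Deviations of a library were log2 CPM, with an offset of 0.5, minus the mean of the other 2 libraries, over list genes of at least 10 CPM, each gene being assigned to the first list that holds it. Limits on counts of 0 used 3 reads, and intervals of single shares are 95% Wilson intervals. Both cover counting error only, as sequencing reads are not independent molecules.

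The steps were tested on simulated data. With a BCV of 0.1, 0.2 and 0.4 drawn around the real means, the estimates were 0.100, 0.199 and 0.394 for Biocodex and 0.100, 0.199 and 0.399 for BY4741. Each simulated feature had the same BCV, while the spread of real BY4741 features fell with abundance. The simulation does not show how the estimate behaves in that case. Lists of 20 genes were drawn among 5898 BY4741 genes, 200 of which were raised. Of 10 raised lists, 4 were called at 2-fold, 9 at 4-fold and 10 at 8-fold, and 1 of 40 unchanged lists was called at each size. Alternatives covered normalization, filters, DESeq2 dispersions, thinning, coding length, near-identical genes and the omission of each library. Versions were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

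Depth limits the comparisons. BY4741 replicates 2 and 3 hold 5181546 and 4581414 reads, so 10 reads there correspond to more CPM than in the other 4 libraries, and the mean of a gene under 10 CPM rests on few reads in them.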

Results

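Yeast mRNA was profiled by RNA sequencing in 6 libraries, 3 from S. boulardii Biocodex, a probiotic yeast, and 3 from S. cerevisiae BY4741, a haploid laboratory strain of the S288C background. According to the labels, the cells had spent 6 h in a medium named ILM and were in mid-exponential growth when pelleted. The series' title sets the work in conditions related to the host, and strain is the factor that its labels vary. The Biocodex libraries held 18529647, 22405430 and 41039732 counted reads in replicates 1, 2 and 3. The BY4741 libraries held 18707708, 5181546 and 4581414. Biocodex files listed 5482 features and BY4741 files 6572 features, under identifiers of different kinds, and 0 identifiers were shared. Gene levels were therefore not compared between the strains. The strains were compared by values of whole libraries, and genes were compared with other genes within BY4741, where 5898 identifiers matched a named gene of the S288C reference R64.

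Reads were concentrated on fewer features in BY4741 than in Biocodex. The 10 most abundant features took 12.5% ± 1.06 (SD, n = 3) of the reads in BY4741 and 8.59% ± 0.464 (SD, n = 3) in Biocodex, a ratio of 1.46, and each BY4741 library lay above each Biocodex library. The single most abundant feature took 1.81% ± 0.180 (SD, n = 3) in BY4741, where it was the pyruvate kinase gene CDC19 or the glyceraldehyde-3-phosphate dehydrogenase gene TDH3, depending on the library. In Biocodex it took 1.205% ± 0.0525 (SD, n = 3) and was listed as KO01_05204, followed by KO01_00245 at 11737 ± 517 CPM (SD, n = 3). These identifiers carry no gene name in the files. The ranks are by reads, not scaled for coding length. Per kb of coding length, TMA10 ranked 1 among BY4741 genes, TDH3 2 and CDC19 9. The 100 most abundant features took 33.1% ± 1.31 (SD, n = 3) in BY4741 and 28.3% ± 0.937 (SD, n = 3) in Biocodex. For the 500 most abundant features the values were 57.5% ± 0.951 and 56.5% ± 0.953 (SD, n = 3 each), which overlapped. The exact two-sided permutation p was 0.1 for the top 10 and for the top 100 (adjusted p 0.125 over 10 measures, Benjamini-Hochberg) and 0.3 for the top 500. With 3 libraries against 3, no p below 0.1 can be reached.

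**Figure D1:**
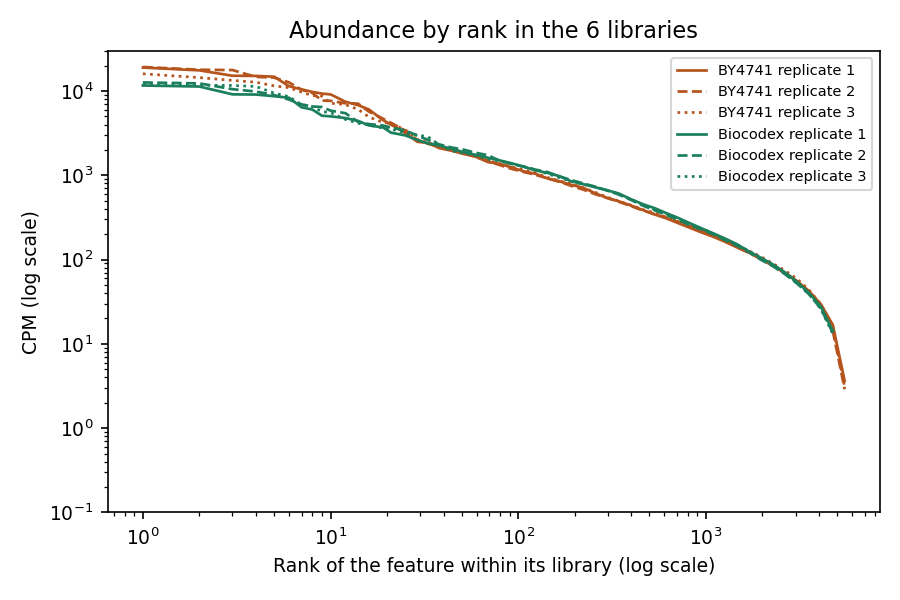
CPM of each feature, on a log scale, against its rank within the library, also on a log scale, for 3 Biocodex and 3 BY4741 libraries (1 line per library). At each rank drawn up to 21 the BY4741 lines lie above the Biocodex lines, and the first 10 ranks hold 12.5% and 8.59% of the reads. At each rank drawn from 59 to 1274 they lie below.

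More features were detected in BY4741, out of a longer list. At least 10 reads were counted on 5638 ± 173 features in BY4741 and on 5407 ± 14.6 in Biocodex (SD, n = 3 each; exact permutation p = 0.1, adjusted p 0.125). These are 85.8% ± 2.63 and 98.6% ± 0.266 of the listed features. The difference of 230.3 features fell to 131 without BY4741 replicate 1, the deepest library of that strain. With each library thinned to the 4581414 reads of the smallest, it was 278. In all 3 libraries of their strain, 537 BY4741 features and 13 Biocodex features had 0 reads.

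Replicate libraries differed more in BY4741 than in Biocodex. The biological coefficient of variation (BCV), edgeR's estimate of the spread between libraries beyond counting error, was 0.327 in BY4741 and 0.147 in Biocodex, a ratio of 2.23. Without Biocodex replicate 1 the Biocodex BCV was 0.0929 and the ratio 3.52. With no filter on low counts the BY4741 BCV was 0.499 and the ratio 3.37, and by DESeq2's median dispersion the values were 0.223 and 0.0968. Among features with a mean of at least 10 CPM, between 10.2% and 17.3% differed over 2-fold between a pair of BY4741 libraries, against 0.223% to 1.26% for Biocodex pairs. Across features, which are not independent replicates, Pearson's r of log2 CPM was 0.949, 0.957 and 0.932 for the BY4741 pairs. For the Biocodex pairs it was 0.987, 0.986 and 0.995. These correlations and the shares over 2-fold include counting error and were not matched for depth, which is lower in BY4741 replicates 2 and 3. The correlations also run over feature lists of unlike length. No pair looked like 1 library sequenced for both, for which chi-square per degree of freedom would lie near 1. Identical counts deposited for both would give a lower value still. The value was at least 42.9 in each pair. The difference in BCV between the strains was not tested.

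**Figure D2:**
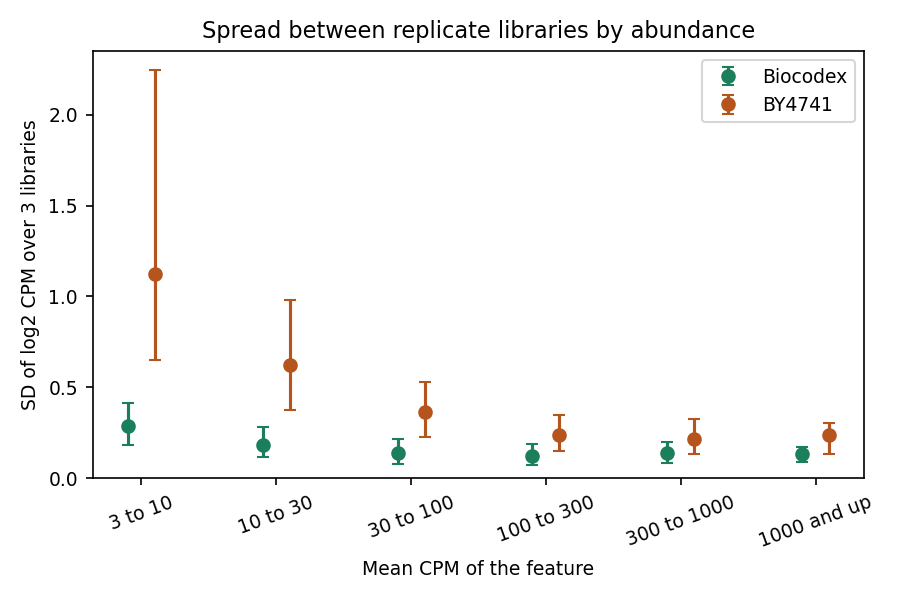
SD of log2 CPM over the 3 libraries of a strain, by class of mean CPM (points are medians over features, bars run from the lower to the upper quartile). BY4741 lies above Biocodex in each class, by 3.89 times between 3 and 10 CPM and by 1.51 times between 300 and 1000 CPM. The SDs are not matched for depth. They include counting error, which is larger in the shallower BY4741 replicates 2 and 3, most of all at low CPM.

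The genes deleted in BY4741 check its labels. LEU2 (YCL018W), URA3 (YEL021W) and MET17 (YLR303W), genes of leucine, uracil and methionine synthesis, had 0 reads in each BY4741 library. A count of 0 allows up to 0.160, 0.579 and 0.655 CPM in replicates 1, 2 and 3, for counting error only. HIS3 (YOR202W), a gene of histidine synthesis of which the strain's allele lacks only a part, had 925, 196 and 285 reads, or 49.8 ± 12.2 CPM (SD, n = 3). These genes were not analysed in Biocodex, whose identifiers name no gene. Genes of the mating type that BY4741 carries were read as well. MFA1 and MFA2, which encode the a-factor pheromone, stood at 144 ± 9.18 and 143 ± 24.9 CPM, and STE2, the receptor of alpha factor, at 65.8 ± 18.3 CPM (SD, n = 3 each). SAG1, the agglutinin of alpha cells, stood at 43.0 ± 3.35 CPM (SD, n = 3). The list of 21 mating genes lay within the random lists, with a median of 51.0 CPM.

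Within BY4741, each of 36 fixed gene lists was set against 10000 random lists of the same size drawn from the 5898 matched genes, whose median level was 60.5 CPM. A list was called above or below when its median lay outside the central 95% of the random lists in each of the 3 libraries. By that rule 17 lists were above and 5 below, 13 were within, and 1 had no measured member. A random list falls outside in a given library in 5% of cases. The percentiles describe levels within these libraries, with no test between groups. A list called above is abundant next to random genes, which does not show that its genes were induced.

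The list of glycolysis and ethanol fermentation had the highest median of the lists. Its 23 genes took 13.2% ± 1.68 (SD, n = 3) of the reads, with a median of 4106 CPM, above each of the random lists in the 3 libraries. CDC19 (YAL038W) stood at 17549 ± 1484 CPM, TDH3 (YGR192C) at 16714 ± 3041, the pyruvate decarboxylase gene PDC1 (YLR044C) at 14163 ± 1275 and the aldolase gene FBA1 (YKL060C) at 13378 ± 2108 (SD, n = 3 each). ADH1 (YOL086C), the alcohol dehydrogenase that forms ethanol, stood at 11849 ± 696 CPM (SD, n = 3). Of the list, 16 genes exceeded 1000 CPM, and PDC5, a second pyruvate decarboxylase gene, was lowest at 9.99 ± 1.14 CPM (SD, n = 3). PDC1 exceeded PDC5 by 1421-fold, from 1213 to 1692 over the libraries.

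Hexose transporter genes were split into a few abundant members and many near 0. The median of the 20 measured genes was 7.71 CPM, below each of the random lists in the 3 libraries. The high-affinity transporter gene HXT7 nonetheless reached 3447 ± 917 CPM, HXT6 2148 ± 629, HXT5 1506 ± 281 and HXT2 1200 ± 236 (SD, n = 3 each). HXT6 and HXT7 are near-identical, so the division of reads between them is uncertain. HXT1, a low-affinity transporter gene induced by high glucose, stood at 10.4 ± 6.84 CPM and HXT3 at 292 ± 98.2 (SD, n = 3 each). The log2 ratio of HXT7 over HXT1 was 8.58 ± 1.14, and of HXT2 over HXT1 7.07 ± 1.13 (SD, n = 3 each). Without replicate 3 they were 7.92 and 6.43, and without replicate 2 the mean of HXT1 was 6.88 CPM. HXT17 had 0 reads and 10 of the members lay under 10 CPM. The list lay within the random lists when genes under 1 CPM, or genes sharing over 50% of their 50-mers with another gene, were left out.

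Isoenzymes of the same step differed in level. The hexokinase gene HXK1, known as repressed by glucose, exceeded HXK2 by 6.11-fold (log2 2.61 ± 0.21, SD, n = 3), and the glucokinase gene GLK1 exceeded HXK2 by 3.75-fold (log2 1.91 ± 0.26, SD, n = 3). ADH1 exceeded ADH2, the alcohol dehydrogenase gene of ethanol oxidation, by 10.4-fold (log2 3.38 ± 0.31, SD, n = 3), with ADH2 at 1148 ± 170 CPM. The acetyl-CoA synthetase gene ACS1 exceeded ACS2 by 5.62-fold (log2 2.49 ± 0.67, SD, n = 3). CIT2, the peroxisomal citrate synthase gene, exceeded the mitochondrial CIT1, with a log2 ratio of CIT1 over CIT2 of -1.88 ± 0.38 (SD, n = 3). COX5B, the subunit gene associated with low oxygen, exceeded COX5A (log2 of COX5A over COX5B -0.74 ± 0.05, SD, n = 3). CYC7, like COX5B a member of the anaerobic list, exceeded CYC1 (log2 of CYC1 over CYC7 -1.66 ± 0.67, SD, n = 3). HMG1 and HMG2, both for HMG-CoA reductase, were close, with a log2 ratio of 0.12 ± 0.08 (SD, n = 3). Each of these ratios kept its direction in 3 of 3 libraries, and an exact two-sided sign test over 3 libraries cannot go below 0.25. In all, 23 pairs were compared.

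**Figure D3:**
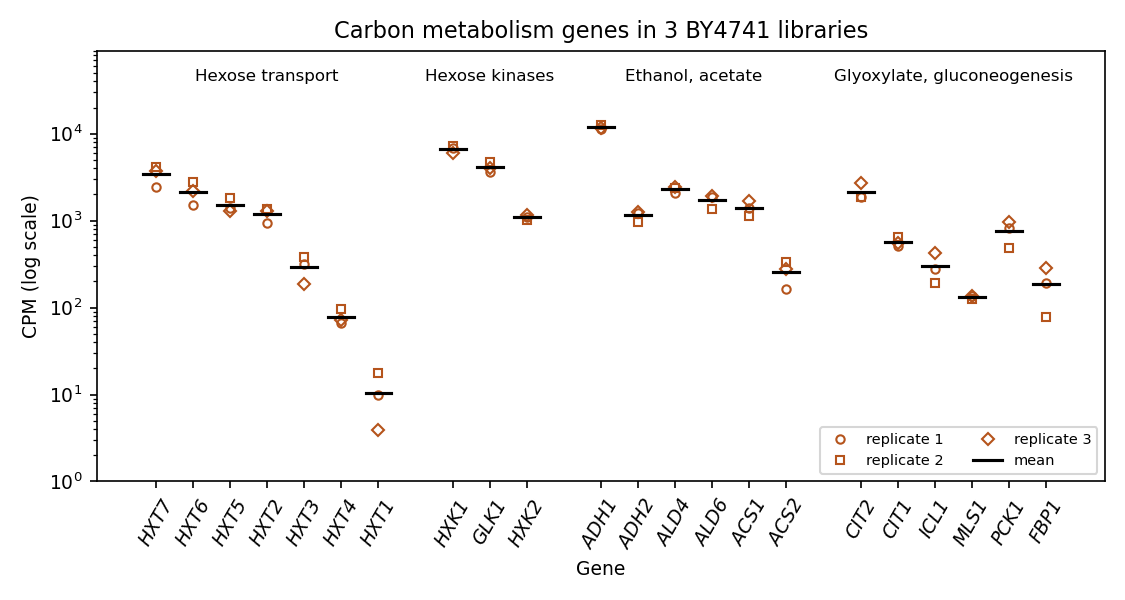
CPM (log scale) of genes of hexose transport, hexose kinases, ethanol and acetate metabolism, and the glyoxylate cycle with gluconeogenesis in the 3 BY4741 libraries (symbols) with their mean (line). HXT7 stands at 3447 CPM and HXT1 at 10.4, HXK1 at 6659 and HXK2 at 1089.

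Genes of acetate metabolism and of the TCA and glyoxylate cycles stood above the random lists. The 16 acetate genes had a median of 570.1 CPM and the 26 genes of the TCA and glyoxylate list, which also holds PCK1 and FBP1 of gluconeogenesis, one of 302 CPM, both above each of the random lists in the 3 libraries. The aldehyde dehydrogenase gene ALD4 stood at 2287 ± 202 CPM, ALD6 at 1714 ± 294 and ACS1 at 1405 ± 275 (SD, n = 3 each). CIT2 reached 2143 ± 484 CPM and the malate dehydrogenase gene MDH2 1122 ± 83.6 (SD, n = 3 each). PCK1, the entry enzyme of gluconeogenesis, stood at 756 ± 248 CPM, ICL1, isocitrate lyase, at 299 ± 118, MLS1, malate synthase, at 132 ± 5.47, and FBP1, fructose-1,6-bisphosphatase, at 186 ± 106 (SD, n = 3 each). The lowest of the acetate genes was ALD5 at 48.5 ± 11.4 CPM (SD, n = 3). The 34 nuclear genes of the respiratory chain and ATP synthase were above with a median of 133 CPM, led by ATP2 at 558 ± 104 CPM (SD, n = 3). Mitochondrially encoded genes were not analysed here.

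Genes known as markers of stationary phase and starvation were abundant, although the labels place the cells in exponential growth. Their 18 members had a median of 630.3 CPM, above each of the random lists in the 3 libraries, and 15 exceeded 100 CPM. GRE1, a hydrophilin gene, stood at 5545 ± 1817 CPM, HSP12, a membrane-protecting heat shock protein gene, at 2856 ± 489, SPG4 at 1956 ± 341 and HSP26 at 1845 ± 423 (SD, n = 3 each). SNO1 was lowest at 50.9 ± 11.1 CPM (SD, n = 3). The 16 glycogen and trehalose genes were above as well, with a median of 515.8 CPM. The glycogen branching enzyme gene GLC3 stood at 1950 ± 248 CPM and the trehalose synthase gene TPS1 at 1565 ± 335 (SD, n = 3 each). The lowest was PGM1 at 14.5 ± 4.64 CPM (SD, n = 3).

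Ribosomal protein genes lay above the random lists, while the list of genes that assemble ribosomes lay within them. The 137 cytosolic ribosomal protein genes took 7.47% ± 1.502 (SD, n = 3) of the reads, with a median of 421 CPM, above each of the random lists. RPL3 led at 3757 ± 516 CPM and RPL22B was lowest at 14.3 ± 12.5 (SD, n = 3 each). The 61 ribosome biogenesis genes had a median of 76.1 CPM, within the random lists, with CBF5, a pseudouridine synthase gene, highest at 281 ± 28.2 CPM (SD, n = 3). The 67 mitochondrial ribosomal protein genes had a median of 53.0 CPM, within, but above per kb of coding length. Membership in the lists explained 10.5%, 17.3% and 10.4% of the variance of the deviations of BY4741 replicates 1, 2 and 3, a share that 0, 0 and 3 of 1000 shuffles of the genes over the lists reached. In BY4741 replicate 2, ribosomal protein genes had a median log2 deviation of -0.58 from the mean of the other 2 libraries, while hexose transporter genes had one of 0.47. In replicate 1, ribosomal protein genes had a median deviation of 0.30, and glycogen and trehalose genes one of -0.39. In replicate 3, the 8 genes assigned to the seripauperin and anaerobic list had a median deviation of 0.75. Stationary phase and starvation markers had one of -0.45. COX5B and CYC7, also in the anaerobic list, were assigned to the respiratory chain list here and went the other way. Their means were 352 and 107 CPM over the 3 libraries, and 365 and 114 without replicate 3. The lists named here were picked as the highest and lowest of each library, among lists with at least 8 genes of 10 CPM or more. A list as high came up in 452, 19 and 2 of 1000 shuffles for replicates 1, 2 and 3, and one as low in 19, 194 and 13. Small lists set the extremes of the shuffles, so these counts are strict for the 137 ribosomal protein genes. The deviations of a gene balance out over the 3 libraries, so a value in 1 library partly restates those of the others. Shuffles also treat genes as independent, which genes regulated together are not.

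Stress and cell wall lists were above. The 38 cell wall genes took 4.35% ± 0.344 (SD, n = 3) of the reads, with the cell wall protein genes SED1 (YDR077W) at 15809 ± 1823 CPM, CCW12 at 6077 ± 408, HSP150 at 4712 ± 1239 and CWP2 at 4238 ± 272 (SD, n = 3 each). The heat shock and folding list had a median of 295 CPM, led by the Hsp70 gene SSB2 at 1487 ± 279 CPM (SD, n = 3). The oxidative defence list had a median of 229.6 CPM, led by SOD1, superoxide dismutase, at 1724 ± 112 CPM (SD, n = 3), with GPX2 lowest at 5.27 ± 4.59. The osmotic and acid list had a median of 152 CPM, led by SPI1 at 1361 ± 421 CPM (SD, n = 3), with STL1, a glycerol transporter gene, at 2.59 ± 3.20 (0.802 without replicate 2). That list and the purine synthesis list, which had a median of 187 CPM and was led by ADE3 at 664 ± 113 CPM (SD, n = 3), lay within the random lists per kb of coding length.

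Lists of amino acid and sterol synthesis, histones, fatty acids, and metal and phosphate response were also above. The 12 genes of branched-chain amino acid synthesis were above, with a median of 308 CPM, led by ILV5 at 1020 ± 194 CPM (SD, n = 3). The 29 ergosterol genes were above, with a median of 138 CPM, led by NCP1 at 997 ± 154 and ERG3 at 703 ± 187 CPM (SD, n = 3 each). The 10 histone genes were above, with a median of 329 CPM. HTA1 exceeded HTA2, the other gene for histone H2A, by 12.2-fold (log2 3.61 ± 0.64, SD, n = 3). The 27 genes listed under fatty acid oxidation and peroxisomes were above with a median of 138 CPM. The 3 most abundant members belong to fatty acid desaturation and synthesis, with OLE1 at 6242 ± 838 CPM, FAS2 at 1774 ± 435 and ACC1 at 1275 ± 219 (SD, n = 3 each). The oxidation genes POT1, FOX2 and POX1 stood at 341 ± 34.6, 340.4 ± 58.7 and 139.0 ± 59.4 CPM (SD, n = 3 each). The call of this list ended without BY4741 replicate 1, per kb of coding length, without genes under 1 CPM and without near-identical genes. The 25 genes of zinc, copper and phosphate response were above, with a median of 151 CPM. The sodium-phosphate transporter gene PHO89 stood at 1735 ± 138 CPM and PHO84 at 648 ± 116 (SD, n = 3 each). The metallothionein genes CUP1-1 and CUP1-2, identical in sequence, stood at 1248 ± 264 and 1240 ± 257 CPM (SD, n = 3 each).

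Nitrogen and iron genes were within by the rule of 3 libraries, with abundant single members. The nitrogen catabolite repressed list had a median of 140 CPM, at percentiles from 78.4 to 100 over the libraries, and the iron regulon one of 120 CPM, at percentiles from 95.4 to 98.9. On mean CPM over the libraries the 2 medians lay at percentiles 99.89 and 99.42, outside the central 95%. Both lists were above without BY4741 replicate 2. Glutamine synthetase, GLN1, stood at 2416 ± 32.6 CPM, the ammonium permease gene MEP2 at 375 ± 297, and the siderophore mannoprotein gene FIT3 at 1879 ± 45.0 (SD, n = 3 each). Without replicate 3, MEP2 stood at 206 CPM. FET3, the multicopper oxidase of iron uptake, stood at 780 ± 218 CPM (SD, n = 3).

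Besides the hexose transporters, the lists of meiosis, seripauperin and anaerobic, subtelomeric and auxotrophic marker genes lay below. The 20 meiosis genes had a median of 8.75 CPM, below each of the random lists, with SPO11 and MEK1 at 0 reads and IME1, the regulator of meiotic entry, at 18.1 ± 6.04 CPM. SPS100, a spore wall gene, was the exception at 613 ± 213 CPM (SD, n = 3 each). The 32 seripauperin and anaerobic genes had a median of 4.27 CPM, below each of the random lists, and 22 lay under 10 CPM. AAC3, the ADP/ATP carrier gene of anaerobic growth, and PAU1, PAU4 and PAU19, near-identical to other genes, had 0 reads. The 4 members of at least 100 CPM included COX5B at 352 ± 25.5, CYC7 at 107 ± 12.7 and ANB1 at 103 ± 14.7 CPM (SD, n = 3 each). The low median therefore does not describe each member. The 23 subtelomeric genes had a median of 21.5 CPM, with COS12 at 0 reads. Both these lists lay within once near-identical genes were left out. The list of the auxotrophic markers was below by its deletions, and without genes under 1 CPM it held too few members.

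Of the remaining lists, galactose and maltose utilisation had a median of 28.7 CPM and methionine and sulfate assimilation one of 31.6 CPM. On mean CPM over the libraries these medians lay at percentiles 2.33 and 1.1 of the random lists, outside the central 95%. Over the libraries the percentiles ran from 0.655 to 4.005 and from 0.435 to 3.21, so both were within by the rule of 3 libraries, and their calls depended on the setting. The former was below without BY4741 replicate 2, per kb of coding length and without genes under 1 CPM. The latter was below without replicate 1, without genes under 1 CPM and without near-identical genes. GAL10 stood at 1.03 ± 1.79 CPM, with reads in replicate 1 alone, and MET30, a ubiquitin ligase subunit gene of the sulfur pathway, at 543 ± 121 (SD, n = 3 each). Polyamine genes (median 111 CPM), histidine, arginine and lysine synthesis (92.8 CPM), pyrimidine metabolism (55.2 CPM), multidrug transporters (46.1 CPM), adhesins (43.0 CPM) and vitamin genes (42.9 CPM) were within. Among them the highest were GAP1 at 492 ± 265, CPA1 at 1080 ± 125, URA2 at 1507 ± 509, PDR5 at 425 ± 208, TIR4 at 204 ± 89.3 and BIO2 at 585 ± 93.0 CPM (SD, n = 3 each).

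**Figure D4:**
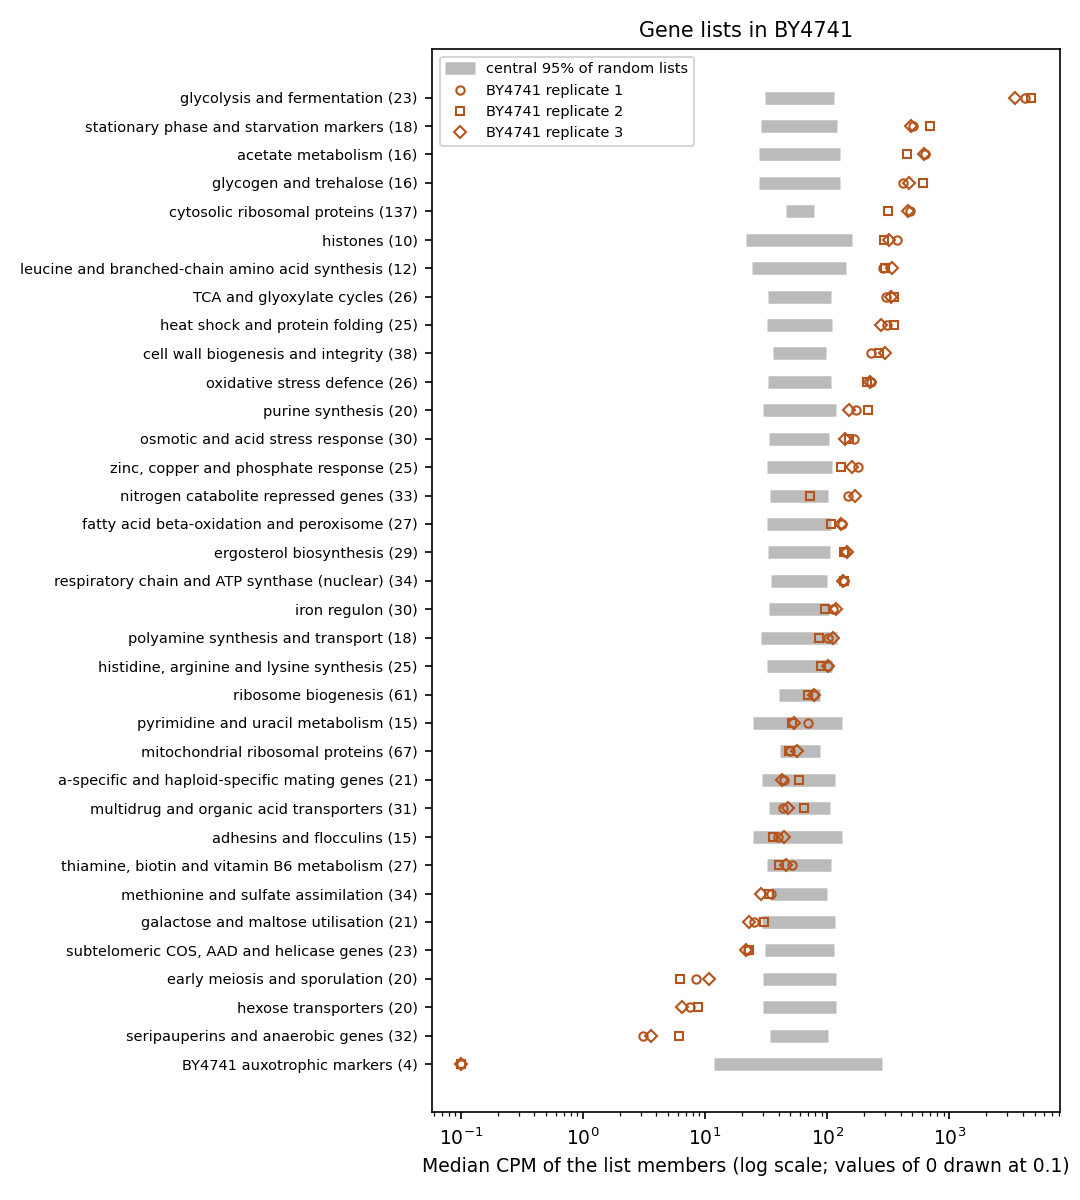
Median CPM of the members of 35 gene lists in each BY4741 library (symbols, log scale, values of 0 drawn at 0.1), with the number of measured members in brackets and the central 95% of medians of 10000 random lists as grey bars, which were drawn for the mean of the libraries. Glycolysis and fermentation lies highest, with a median of 4106 CPM, and 5 lists lie below the bars in each library.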

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

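Reads on BY4741 identifiers without a gene in the reference table entered no list or pair. These 674 identifiers held 0.117% (95% Wilson interval 0.116 to 0.119), 0.170% (0.167 to 0.174) and 0.136% (0.133 to 0.139) of the reads in replicates 1, 2 and 3, far above the 3 reads that a count of 0 allows, which is why they are listed here. The highest was YDR133C at 355 ± 30.7 CPM, followed by YAL037C-B at 69.9 ± 62.6 CPM (SD, n = 3 each). At least 10 reads were found on 202, 137 and 108 of them. No explanation of these reads was tested.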

How the results depend on the processing

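All the alternatives reported here were chosen after the data had been seen. The planned ones concern gene tests between strains, which the unshared identifiers ruled out, and were not run. The labels tie the replicate numbers of the strains to no shared culture or day, and without shared features the pairing could not be checked. With the replicate number as a block, the mean ratio within pairs was 1.47 for the top 10 and 1.17 for the top 100 (higher in 3 of 3 pairs, exact permutation p = 0.25 each, the smallest possible) and 1.02 for the top 500 (higher in 2 of 3 pairs, p = 0.5). The difference in detected features was 230.3 (higher in 3 of 3 pairs, exact permutation p = 0.25). The block changed no call. The ratios of read shares and the difference in detected features kept their direction under thinning, without near-identical genes (ratios only), with at least 1 read (features only) and without each library. Their p-values cannot pass a threshold of 0.05 in this design, so they say nothing about stability. The top-10 ratio ran from 1.42 to 1.53 without single libraries. For the BCV, where 1 SD over the omissions of single libraries was taken as the spread, Biocodex gave 0.0968 and BY4741 0.223 by DESeq2's median dispersion, and BY4741 gave 0.499 with no filter, with a strain ratio of 3.37. The cause was not tested. Without single libraries the Biocodex BCV ran from 0.0929 (without replicate 1) to 0.173, that of BY4741 from 0.311 to 0.371 and the ratio from 1.89 to 3.52, above 1 in each. Lists above numbered 15 to 19 under the alternatives, against 17, and of these 17 at least 14 kept the call. Lists below numbered 3 without near-identical genes, against 5, because members were removed, and 5 or 6 otherwise. These counts include lists newly called. Of the 5 lists below, 2 kept the call without near-identical genes, 1 of them the auxotrophic markers, and 3 without genes under 1 CPM. All 5 kept it per kb of coding length and without single libraries. Of the log2 ratios of gene pairs, none turned, 91 alternative values moved by less than 1 SD, which the omission of 1 library cannot exceed, and 1 moved by more (GPD1 over GPD2, -0.73, per kb -0.56). Per kb of coding length, the 100 most abundant BY4741 genes held 41.0% of length-scaled reads, against 33.1% of reads.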

Other observations

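Some copies of the same gene received unequal counts in BY4741. The helicase gene YRF1-1 had 34394, 10531 and 8378 reads in replicates 1, 2 and 3, while YRF1-5, with an identical coding sequence, had 436, 109 and 79. In contrast, TEF1 and TEF2, near-identical genes of elongation factor 1-alpha, stood at 8832 ± 1179 and 8345 ± 1071 CPM (SD, n = 3 each). For the asparaginase copies, ASP3-1 had 6255, 1913 and 1644 reads, ASP3-2 6389, 1908 and 1590, and ASP3-3 6532, 1955 and 1627. Only ASP3-4 lay apart, with 492, 162 and 116. Several abundant genes belonged to no fixed list and were picked after their values were seen. TMA10, a ribosome-associated protein gene, stood at 8213 ± 498 CPM, UTH1 at 4159 ± 672 and SPO24 at 2531 ± 146 (SD, n = 3 each).

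The larger spread between BY4741 libraries than between Biocodex libraries (BCV 0.327 and 0.147) was weighed against 4 explanations, whose predictions were written before the deciding values were computed. Counting error from fewer reads does not account for it. Biocodex counts thinned to the BY4741 totals gave a BCV of 0.138, or 0.423 of the BY4741 value. The BCV leaves counting error out, so thinning could hardly change it, and other traits of shallow libraries are not covered. A surplus of rarely read features does not account for it either. In each of 6 abundance classes the spread was at least 1.51 times larger in BY4741. It was predicted that a different growth state would let the gene lists explain most of the variance of a library's deviations. They explained 10.5%, 17.3% and 10.4% in replicates 1, 2 and 3 (reached by 0, 0 and 3 of 1000 shuffles). This falls short, but the lists mix members of unlike regulation, such as HXT1 and HXT7, and the variance includes noise of single genes. A growth state need not reach the predicted share, so the test leaves it open as the main cause or as a part. Few RNA molecules behind the BY4741 reads may be a part of the cause, since excess variance fell with abundance with a slope of -0.65 (log10 on log10; -0.59 to -0.76 over the pairs), against -0.19 in Biocodex and -0.20 in thinned Biocodex. Values picked after they were seen argue against this as the whole cause. The median SD of BY4741 was 0.214 between 300 and 1000 CPM and 0.235 above, where it was still 1.76 times that of Biocodex. Keeping only features of at least 10 CPM gave a BY4741 BCV of 0.339. That fit held 5131 features, against 5299 in the main fit, so it could hardly differ and decides nothing here. Why the strains would differ in the slope is untested, and a difference between the strains themselves stays open and untested.

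The larger share of reads in the 10 most abundant features in BY4741 libraries was seen first, and the predictions were then written before the tests were run. The number of reads drawn is argued against as the cause, since the ratio of strain means was 1.46 after thinning to the smallest library. Random thinning hardly changes the share of abundant features, so the test says nothing of other differences between shallow and deep libraries. Without near-identical BY4741 genes the ratio was 1.51, which argues against reads on such genes in BY4741. Copies in Biocodex could not be examined, as its identifiers name no gene. Of 100 random reductions of the BY4741 list to the Biocodex length, 0 gave a ratio below 1.1 (range 1.27 to 1.76). Random removal lowers the reads of abundant features and the total together. These draws therefore cannot decide whether the Biocodex list lacks particular abundant features. Differences in annotation or counting between the strains' tables were not tested, so they or a biological difference between the strains may explain it.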
